A study of Mus musculus with 2 samples.

How the data were processed

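H3K4me3 ChIP-seq peaks from stomachs of mouse embryos at day 14.5 were analyzed. Per the labels, the group has 2 biological replicates, each from tissue pooled over male and female embryos, with a fragment size range of 300 to 500 bp. Both samples carry the same donor label, and neither the number of embryos in a pool nor whether the pools came from separate litters is given in the sources used here, so the spread between replicates describes only these samples. The authors deposited 4 peak lists on the mm10 genome build in the narrowPeak format. Per the file headers, each replicate's list was derived from that replicate's own filtered alignments and 1 further file, a different file for each replicate, so peaks were called per sample. The pooled list was derived from the alignments of both replicates, and the replicated list from the pooled list and both replicate lists, per the file headers. Every replicated peak is also a pooled peak, with the same position and values. The aligner, the peak caller, its thresholds and the rule for calling a peak replicated are not given in the sources used here.

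The authors' peak lists give each peak a signal value, which is an enrichment score of the authors' caller and is scaled within each list. It was used only to describe and rank peaks within a list, and values from both replicates are printed side by side without a test between them. The deposited −log10 q of each peak, also per list, served for ranking and as a stricter threshold. The summit offsets that the authors' files also hold were not used. The lists hold no read counts, so depth is unknown, and no interval or floor that needs a depth is given. The binomial intervals on overlap shares cover the counting of peaks only. The median −log10 q was 12.2 in replicate 1 and 49.0 in replicate 2, and 38.1% and 22.5% of their peaks lay below 5.

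Gene positions were taken from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names, and promoter sequence from the GRCm38 reference. All peaks on chromosomes 1 to 19, X and Y ended within the reference chromosome lengths. Coordinates are counted from 1. Protein-coding genes were taken by symbol. A gene was called marked when a peak overlapped any of its annotated transcript starts extended by 1 kb on each side, and its domain was the widest run of peaks at its starts after joining peaks 1 kb or less apart. A wide promoter peak can thus mark a close neighbor, so whether a start base itself lay inside a peak was also recorded. The CpG observed/expected ratio was computed over 500 bp on each side of every start, and a gene's highest value was used. Peaks were compared by an overlap of at least 1 bp. Chance overlap came from 100 rotations of a list, each chromosome shifted by 1 random offset.

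The 25 gene lists, the tests and the rule for named genes were set before the data were examined. The lists cover epithelial, mesenchymal, muscle, neural, vascular and blood cells of the stomach, mature gastric and squamous cells, other organs, the germline, olfactory receptors, sex-linked genes, housekeeping and cell cycle genes, gut patterning signals and Hox genes. No gene stands in more than 1 list. Marked shares were tested with two-sided Fisher exact tests of list members against all other protein-coding genes. Median domain widths of lists with at least 5 marked members were tested against 10000 random lists of marked genes, where the smallest two-sided p is 0.0002. Genes marked in a single replicate were tested with exact McNemar tests. Each family was adjusted over its lists by the Benjamini-Hochberg method, with a threshold of 0.05. Genes at a shared domain are not independent, which affects the Hox list most. The p-values measure agreement between genes or between these libraries, not between animals.

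The text names the 20 genes with the widest domains (1 per domain, with those sharing it) and the 10 with the highest signal value. From each list it names up to 4 marked members with the widest domains and up to 4 unmarked members in alphabetical order. For the endothelial and mature gastric lists, members marked in only 1 replicate are named beyond that rule. Any members may be named for lists of fewer than 16 genes, the Hox genes and the sex-linked list. It also names the 5 genes with the highest signal value among those marked in each replicate only, and the 10 strongest replicated peaks more than 1 kb from any start. Of the listed symbols, Cblif was covered by its older symbol Gif, and Xist and Tsix, which are not protein-coding, were described outside the tests.

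The alternatives were another overlap rule, −log10 q thresholds of 2 and 5, promoter windows of 500 bp and 2 kb, the outermost start alone, the pooled list, each replicate's list alone (without replicate 1, or without replicate 2), joining of touching peaks only or within 3 kb, and random lists matched on CpG ratio in 10 bins. Requiring the start base inside a peak, and matching widths on the number of CpG within 5 kb, were added after seeing the data. The list tests were checked on simulated data, with lists of 20 genes drawn from the 21911 genes or the 14470 marked genes. In 3 of the 5 simulations 32 of 100 lists were altered, to be fully marked, rarely marked or wide, and in the others none. All altered lists were called, and 0% to 1.47% of the unaltered ones. Smaller differences and lists of neighboring genes were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Repeated promoter sequence was judged on 50-mers, at steps of 25 bp. The read length is not given in the sources used here and would change which promoters cannot be placed. Peaks on scaffolds outside the assembled chromosomes were left out of gene-based results.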

Results

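H3K4me3, the trimethylation of lysine 4 on histone H3 that marks active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the mouse stomach at embryonic day 14.5. At this age the stomach is an epithelial tube inside a thick mesenchyme that is forming smooth muscle, ahead of the maturation of its acid and enzyme secreting cells. The labels give 1 group of 2 biological replicates, each a pool of stomachs from male and female embryos, so no contrast between conditions was available. The questions that the design allows are how far the replicates agree, where the mark lies, and which genes and cell type programs carry it or lack it. Replicate 1 has 29444 peaks over 30.2 Mb and replicate 2 has 25907 peaks over 35.5 Mb. The list that the authors called replicated holds 20591 peaks over 36.0 Mb, or 1.32% of the assembled chromosomes. Read depth is unknown, since the peak lists hold no read counts.

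The replicates shared their strong peaks and differed in their weak ones. Of the replicate 1 peaks, 82.1% overlapped a replicate 2 peak by at least 1 bp (95% exact binomial interval 81.7 to 82.5), and 79.8% of the replicate 2 peaks overlapped a replicate 1 peak (79.3 to 80.3). Over 100 random rotations of the replicate 1 list along the chromosomes, these shares averaged 2.38% and 2.54%. The lists covered 28.0 Mb in common out of a union of 37.6 Mb, a Jaccard index of 0.745 against at most 0.00813 in the rotations. With each list split into 10 equal groups by −log10 q, all peaks in groups 1 to 4, the strongest, overlapped the other list, while 33.5% of group 10 of replicate 1 and 23.4% of that of replicate 2 did. Peaks found in both replicates were wider, with a median of 1031 bp against 206 bp for the remaining peaks of replicate 1 and 1492 bp against 290 bp in replicate 2. Of the replicated peaks, 95.5% overlapped a replicate 1 peak and 99.2% a replicate 2 peak.

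**Figure D1:**
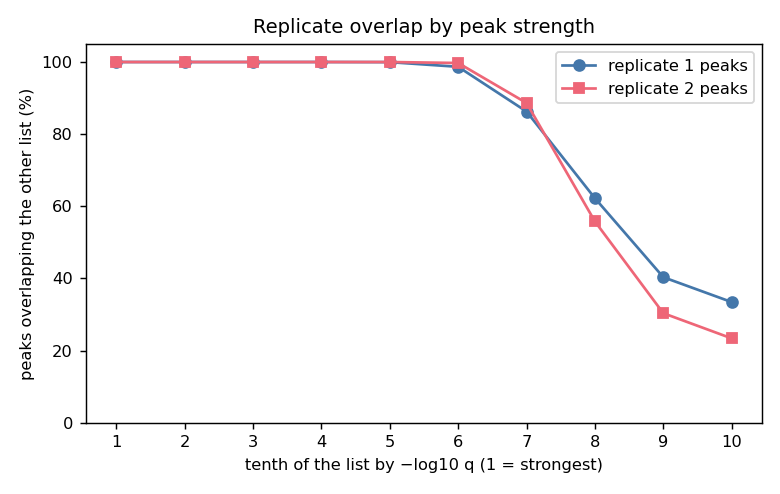
The share of each replicate's peaks (y axis, percent) that overlap the other replicate's list by at least 1 bp, for 10 equal groups of the list ranked by −log10 q (x axis, 1 is the strongest), with 1 line per replicate. Overlap is 100% in groups 1 to 4 and drops to 33.5% and 23.4% in group 10 of replicates 1 and 2.

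H3K4me3 lay mostly at transcript starts. Of the 20579 replicated peaks on the assembled chromosomes, 78.0% lay within 1 kb of an annotated start, 11.2% elsewhere in a gene and 10.8% between genes. Rotated peaks reached a start in 10.6% of cases on average and in 11.9% at most. In the lists of the single replicates the share at starts was 65.5% and 70.2%. Peaks at starts had a median width of 1854.5 bp and a median signal value of 29.8, against 723 bp and 5.81 for the 4533 peaks away from starts. By gene class, 66.0% of protein-coding genes, 34.8% of antisense genes, 13.8% of long intergenic non-coding genes and 1.60% of processed pseudogenes had a replicated peak at a start.

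The 10 strongest replicated peaks away from starts had signal values of 40.5 to 48.6, above the median of 29.8 at starts. All 10 were called in both replicates, and 3 lay inside a protein-coding gene. The first lay on chromosome 1 from 171037631 to 171039022 (mm10), outside protein-coding genes, 18711 bp from the nearest protein-coding start, that of the Fc receptor gene Fcgr4, with a signal value of 48.6. The next was inside Prdm2, which encodes a histone methyltransferase, on chromosome 4 from 143160792 to 143162733, with a value of 48.2. Another was nearest to Arhgap32, at a distance of 81934 bp, on chromosome 9 from 32031640 to 32034202, with a value of 47.6. Others lay inside Nup160 (46.0), nearest to Ppara (45.1), Tln2 (44.9), Zfp869 (44.3), Macf1 (42.1) and Zfp213 (40.5), and inside Ldb3 with 9230112D13Rik as the nearest gene (41.3). From the nearest annotated start of any gene, the Nup160, Macf1, Zfp213, Prdm2 and Zfp869 peaks lay 1300, 1882, 2922, 3870 and 4270 bp away. The rest lay 9666 bp to 65425 bp away. The Ppara peak, on chromosome 15 from 85669627 to 85674020, was the widest of the 10 at 4394 bp.

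A replicated peak marked 14470 of 21911 protein-coding genes, and the replicates alone marked 66.4% ± 0.704 (SD, n = 2). Replicate 1 marked 14439 genes and replicate 2 marked 14657, with 14353 in common. Across the genes marked in both, which are not independent replicates, the peak signal values had a Spearman correlation of 0.764 and the domain widths of 0.903. Domains were wider in replicate 2 at 82.2% of these genes, with medians of 1859 bp and 2141 bp in replicates 1 and 2. The marked share was higher at promoters of higher CpG content. With genes split into 10 equal groups by CpG observed/expected ratio, 0.730% were marked in group 1, the lowest, 17.5% in group 3 and 55.0% in group 4, against 90.3% in group 5 and 99.5% in group 10. The median domain was 1672.5 bp over the 16 marked genes of group 1, 1254 bp in group 2, 1155 bp in group 3 and 2778 bp in group 10.

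**Figure D2:**
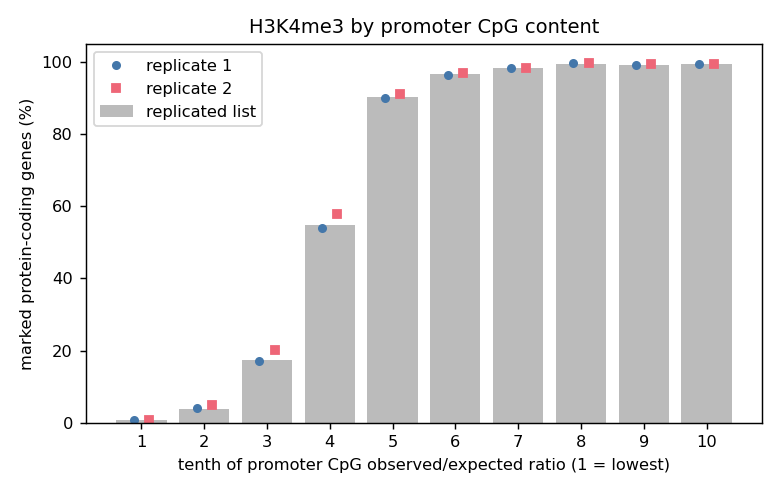
The percentage of protein-coding genes with an H3K4me3 peak within 1 kb of a transcript start (y axis) in 10 equal groups by promoter CpG observed/expected ratio (x axis, 1 is the lowest), as bars for the replicated list and points for each replicate. The share goes from 0.730% to 99.5%, with the steepest steps between groups 3 and 5.

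Of the 25 gene lists fixed before the data were examined, 8 were marked more often than other protein-coding genes, 8 less often, and 9 did not pass (two-sided Fisher exact tests, Benjamini-Hochberg adjusted over the lists). The lists differ in promoter CpG content, and against random lists matched on it only smooth muscle remained among the 8 more often marked lists, and germline and olfactory receptor genes among the 8 less often marked. For gut mesenchyme, gut patterning, housekeeping, cell cycle and Hox genes matched lists were so often fully marked that even a share of 100% would not have passed. The endoderm factor and epithelial lists were fully marked, the highest share possible, and did not pass after adjustment. The matched comparison added endothelium to the more often marked lists and the Y-linked and X-inactivation list to the less often marked. The median CpG ratios of smooth muscle (0.485) and endothelium (0.484) lay near the upper end of group 4 (0.341 to 0.497). Marking was 55.0% in group 4 and 90.3% in group 5, so CpG differences within a group may add to these 2 calls. Of the 18 lists with at least 5 marked members, 9 had wider domains than random lists of marked genes and 1 had narrower domains (two-sided permutation tests, adjusted likewise). Genes are not replicates, so these tests describe these libraries.

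**Figure D3:**
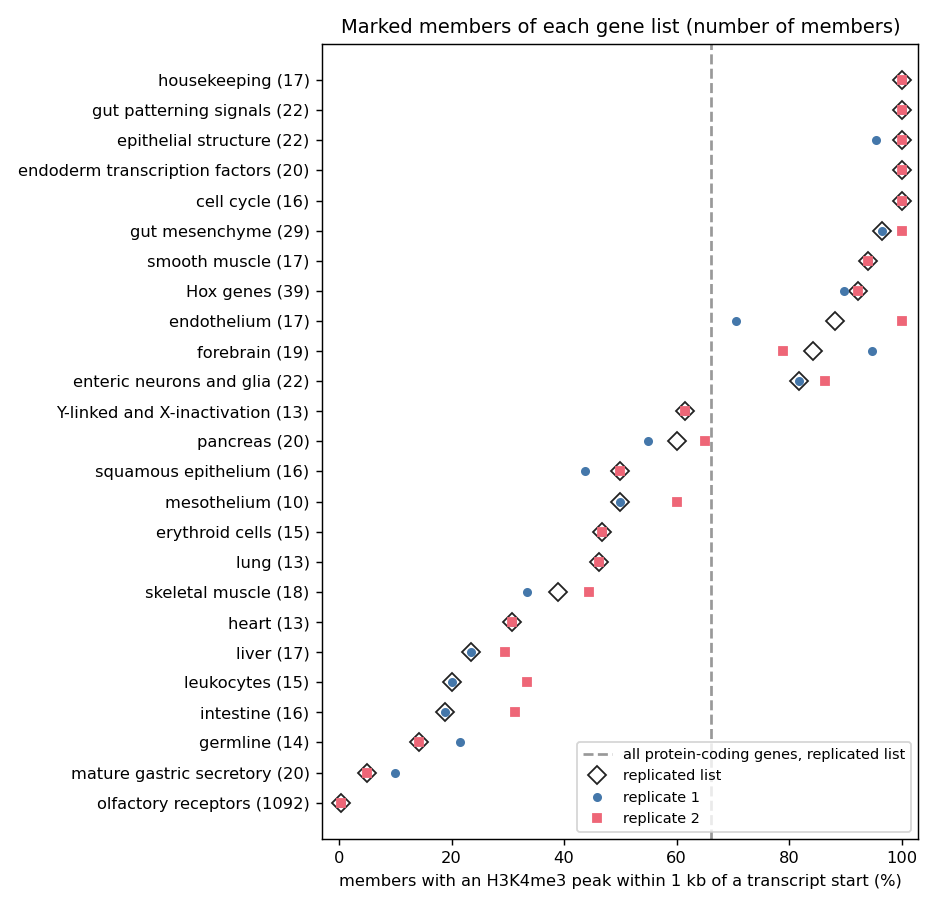
The percentage of each list's members that have an H3K4me3 peak within 1 kb of a transcript start (x axis), for the replicated list (open diamonds) and each replicate (filled points), with the number of members in parentheses. The dashed line is the 66.0% of all protein-coding genes in the replicated list. Epithelial, mesenchymal and smooth muscle lists lie at the right and mature gastric genes at 5.0%.

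Every one of the 20 endoderm transcription factor genes was marked, against 66.0% of other genes (Fisher exact, adjusted p = 0.00104). Their domains were wide, with a median of 4981.5 bp (4776 bp in replicate 1 and 4873.5 bp in replicate 2) against 2150 bp in random lists of marked genes. The widest were at Foxa1, a pioneer factor of foregut endoderm, with 13213 bp, and at the GATA factors Gata6 with 11417 bp and Gata4 with 10087 bp. Sox2, a determinant of foregut and stomach identity, followed with 8862 bp (6964 bp and 8597 bp in replicates 1 and 2). The permutation test gave the smallest p that 10000 random lists allow, 0.0002, or 0.000720 adjusted. The call for marking was lost against CpG-matched lists, which averaged 87.4% (permutation, adjusted p = 0.139). All members were marked and no higher share was possible, so this comparison was not able to keep the call. The width call held under every alternative run.

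All 22 epithelial structure genes were marked as well (Fisher exact, adjusted p = 0.000530), and replicate 1 marked 21 of them. The widest domains lay at Esrp1 and Esrp2, regulators of epithelial splicing, with 4798 bp and 4519 bp, at Cgn, which encodes the tight junction protein cingulin, with 4621 bp (2170 bp and 4557 bp in replicates 1 and 2), and at the keratin gene Krt19 with 3748 bp (2294 bp and 3748 bp). The median of 2752.5 bp exceeded the 2150.75 bp of random lists (permutation test, adjusted p = 0.0389). Against CpG-matched lists, which averaged 84.3%, the permutation adjusted p for marking was 0.0550, and no share above full marking was possible. The width call ended without replicate 2 (0.119), with a −log10 q of at least 5 (0.0836) and against lists matched on CpG number (0.0889). The excess in width was then 434 bp, 542.25 bp and 460.5 bp, against 601.75 bp.

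Genes of mature gastric secretory cells were almost free of the mark, with 1 of 20 marked against 66.1% of other genes (odds ratio 0.0270, 95% interval 0.000650 to 0.170, Fisher exact, adjusted p = 2.05e-07). Unmarked members included Atp4b, a proton pump subunit of acid-secreting cells, the chitinase gene Chia1, and the hormone genes Gast and Ghrl. The member marked in the replicated list was Atp4a, the catalytic proton pump subunit, with a domain of 1259 bp (816 bp and 1218 bp in replicates 1 and 2). At Atp4a only the downstream group of annotated starts, from position 30717832 to 30722388 of chromosome 7, was marked. The upstream group from 30712209 was not. Replicate 1 marked 2 members, as Pga5 was marked there and in neither replicate 2 nor the replicated list. These genes have CpG-poor promoters, with a median CpG ratio of 0.254, and against CpG-matched lists the permutation adjusted p was 0.160.

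Squamous genes, which mark the epithelium of the mouse forestomach, split evenly, with 8 of 16 marked (Fisher exact, adjusted p = 0.218). Marked members with the widest domains were Pax9 (3745 bp), the basal cell regulator Trp63 (2916 bp, or 1242 bp and 2844 bp in replicates 1 and 2), Krt15 (2893 bp) and Perp (2883 bp, or 1201 bp and 2754 bp). Unmarked members included Col17a1, Dsg3, Krt13 and Krt14. Their median width of 2848 bp did not pass the test (permutation, adjusted p = 0.159), and did against lists matched on CpG ratio (permutation, adjusted p = 0.0317). The difference to random lists turned from 696.5 bp to -611 bp without replicate 2 (median 1242 bp) and to -538.5 bp with only touching peaks joined, and was 92.75 bp with a −log10 q of at least 5.

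The gut mesenchyme genes had the widest median domain of the 18 lists tested for width. Of the 29, 28 were marked (Fisher exact, adjusted p = 0.000530), and the remaining gene, Hand1, was marked in replicate 2 only. The median domain was 7862 bp (6147.5 bp and 7824 bp in replicates 1 and 2) against 2147 bp in random lists (permutation test, adjusted p = 0.000720). Meis2 carried 21412 bp and Ptch1, the Hedgehog receptor that is itself a target of the pathway, 19817 bp. Tbx2 and Meis1 followed with 15910 bp and 15440 bp. CpG-matched lists averaged 92.7% marked, which even full marking would not pass, while the width call held under every alternative run, with a median of 5762 bp where only touching peaks were joined.

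Smooth muscle genes were marked at 16 of 17 members, all but Kcnmb1 (Fisher exact, adjusted p = 0.0296), and this exceeded CpG-matched lists too, which averaged 61.1% (permutation, adjusted p = 0.00167). The widest domains were at Tpm2, a tropomyosin gene, with 5888 bp, at the myosin light chain gene Myl9 with 5597 bp, at Smtn with 4863 bp and at the transcription factor gene Srf with 4854 bp. The median of 4110 bp exceeded the 2155.75 bp of random lists (permutation test, adjusted p = 0.000720). With the start base itself required inside a peak the marking call ended (0.0675) at a difference to other genes of 23.8 points, against 28.1 points. With only touching peaks joined the width excess over random lists fell from 1954.25 bp to 420.75 bp and its call ended (0.222).

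Genes of the signals that pattern the gut were marked at all 22 members (Fisher exact, adjusted p = 0.000530), against 95.6% on average in CpG-matched lists, a comparison that full marking cannot pass. Their median domain was 4358.5 bp (3273 bp and 4847 bp in replicates 1 and 2), wider than in random lists by 2205 bp (permutation test, adjusted p = 0.000720) and by 1421 bp without replicate 2. Fgfr2 had 9854 bp, Shh, the Hedgehog ligand of gut epithelium, 9392 bp (5016 bp and 10219 bp in replicates 1 and 2), Wnt5a 8453 bp and Fgf9 7435 bp.

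**Figure D4:**
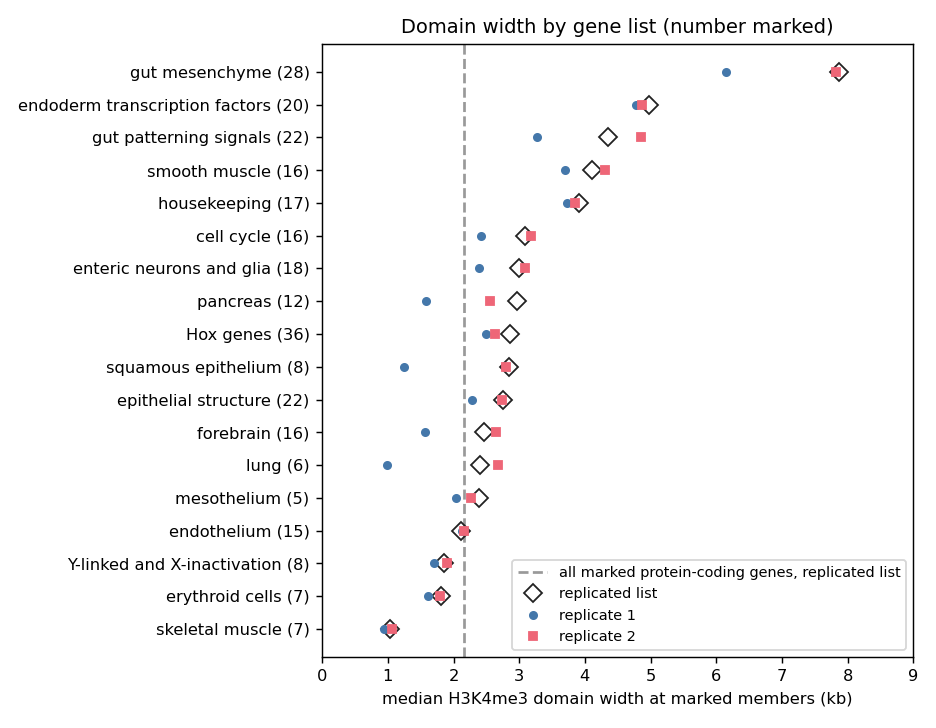
Median H3K4me3 domain width in kb (x axis) over the marked members of each list, for the replicated list (open diamonds) and each replicate (filled points), with the number of marked members in parentheses. The dashed line is the median of all marked protein-coding genes, 2152 bp. Gut mesenchyme genes lie farthest right, at 7862 bp.

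Markers of enteric neurons and glia were marked at 18 of 22 members, which did not pass the test (Fisher exact, adjusted p = 0.208). Hand2, needed for enteric neuron differentiation and also active in mesenchyme, had 12309 bp, the glial cell line-derived neurotrophic factor coreceptor gene Gfra1 6309 bp, and the autonomic neuron factors Phox2a and Phox2b 4605 bp (2074 bp and 1841 bp in replicates 1 and 2) and 4207 bp. The unmarked members were Dbh, Nos1, Plp1 and Vip. Their median domain of 2991.5 bp exceeded random lists (permutation test, adjusted p = 0.0124), a call that ended with only touching peaks joined (0.543), without replicate 2 (0.0889), with a −log10 q of at least 5 (0.114) and against lists matched on CpG number (0.272). The excess was then 213 bp, 544 bp, 527 bp and 426 bp, against 835.5 bp.

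Endothelial genes were marked at 15 of 17 members (Fisher exact, adjusted p = 0.104), with Fli1 (5789 bp), Esam (4476 bp), the vascular growth factor receptor gene Kdr (3970 bp) and Gata2 (3918 bp) the widest. Replicate 1 marked 12 of them and replicate 2 marked 17, and the 5 discordant genes, Cdh5, Emcn, Robo4, Tek and Tie1, were all marked in replicate 2 only (exact McNemar p = 0.0625, the smallest that 5 genes allow). Without replicate 1 the list was marked more often than other genes (Fisher exact, adjusted p = 0.00347), as it was against CpG-matched lists, which averaged 58.5% (permutation, adjusted p = 0.0112). Without replicate 2 the difference to other genes fell from 22.2 to 4.69 points. The median width did not pass (2114 bp against 2152 bp, permutation test, adjusted p = 0.910), and its difference of -38.0 bp turned positive under all but 1 of the alternatives, at 13 bp to 741 bp.

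Mesothelial genes were marked at 5 of 10 members, namely Wt1 (8369 bp), Podxl, Tbx18, Bnc1 and Lrrn4, and not at Gpm6a, Msln, Muc16, Upk1b and Upk3b (Fisher exact, adjusted p = 0.351). Leukocyte genes were rarely marked, at 3 of 15 members (Fisher exact, adjusted p = 0.000962). These were Runx1 (6524 bp), Ikzf1 (2188 bp) and Coro1a (1300 bp, or 796 bp and 1967 bp in replicates 1 and 2), while Ptprc, Spi1, Csf1r, Cd68, Aif1, Cx3cr1, Tyrobp, Fcer1g, Itgam, Vav1, Laptm5 and Lyz2 were not. Erythroid genes were marked at 7 of 15 (Fisher exact, adjusted p = 0.208), namely Tal1 (3516 bp), Ank1 (2092 bp), Epor (2071 bp), Klf1 (1808 bp), Sptb, Gypa and Nfe2, and not at Alas2, Gata1, Slc4a1, Spta1 and the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt. Whether repeated promoter sequence hid a peak at the globin genes was not examined. Replicate 2 marked 5 leukocyte genes, with Fcer1g and Vav1 (Fisher exact, adjusted p = 0.0186 without replicate 1), and the call ended against CpG-matched lists (0.923). The widths of mesothelial and erythroid domains did not pass (permutation tests, adjusted p = 0.672 and 0.470), and their differences to random lists, 239 bp and -358 bp, turned to -72.0 bp and 10 bp against lists matched on CpG ratio.

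Liver and intestinal genes were marked less often than other genes, and pancreatic genes did not pass. Liver genes were marked at 4 of 17 (Fisher exact, adjusted p = 0.00104), with the transcription factor genes Onecut1 (6422 bp) and Prox1 (5224 bp, or 2697 bp and 7784 bp in replicates 1 and 2) the widest, followed by Apoh (2691 bp) and Ttr (491 bp, unmarked in replicate 1), and Afp, Ahsg, Alb and Apoa1 unmarked. The Apoh peak lay at the first annotated start, at position 108343354 of chromosome 11, and not at the downstream groups. Intestinal genes were marked at 3 of 16 (Fisher exact, adjusted p = 0.000530), which were the homeobox gene Cdx2 (2535 bp), Cdx1 (788 bp, or 274 bp and 726 bp) and Satb2 (4843 bp), with Alpi, Cdh17, Fabp1 and Fabp2 unmarked. Replicate 2 marked 5 intestinal genes (Fisher exact, adjusted p = 0.0104 without replicate 1). Pancreatic genes were marked at 12 of 20 (Fisher exact, adjusted p = 0.664), led by Mnx1 (7993 bp), Pdx1 (5141 bp, or 2471 bp and 5434 bp), Nkx6-1 (4812 bp) and Insm1 (4555 bp), with Cel, Cela1, Cpa1 and Gcg unmarked. The median pancreatic width of 2966 bp did not pass (permutation test, adjusted p = 0.0501), and did with peaks within 3 kb joined (0.0124) and against lists matched on CpG ratio (0.0144). The difference to random lists, 809.5 bp, turned to -455.5 bp with only touching peaks joined and -279 bp without replicate 2, and fell to 426 bp without replicate 1, 74.5 bp against lists matched on CpG number and 71 bp with a −log10 q of at least 5. Against CpG-matched lists the marking calls for liver (0.282) and intestine (0.139) ended.

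Lung genes were marked at 6 of 13 (Fisher exact, adjusted p = 0.194). These were Etv5, Sftpc, Foxj1, Nkx2-1, Hopx and Aqp5, while Ager, Lamp3, Napsa, Scgb1a1, Sftpa1, Sftpb and Sftpd were not. At Sftpc no start base lay inside a peak, and the peak came within 1 kb of it in replicate 2 and in the replicated list. Heart genes were marked at 4 of 13 (Fisher exact, adjusted p = 0.0261), namely Ryr2, Tbx5, Tbx20 and Tnni3, and not at Ankrd1, Myh6, Myh7, Myl2, Myl7, Nppa, Nppb, Pln and Tnnt2. At Tbx5 and Tnni3 no start base lay inside a peak, which leaves 2 of 13. Skeletal muscle genes were marked at 7 of 18 (Fisher exact, adjusted p = 0.0352), led by Mylpf (4869 bp), Actn3 (2168 bp), Ckm (1212 bp) and Pax7 (1038 bp, or 448 bp and 904 bp in replicates 1 and 2), with Acta1, Casq1, Myf5 and Myh3 unmarked. Mylpf shares its domain with Tbc1d10b, whose start lies nearer the middle. At Ckm no start base lay inside a peak, and 5 of the 18 members had a start base in one. Domains of the marked skeletal muscle genes were narrow, with a median of 1038 bp against 2156 bp (permutation test, adjusted p = 0.00617), a difference of -1118 bp that was -693 bp against lists matched on CpG ratio. The marking calls for heart (1.00) and skeletal muscle (0.965) ended against CpG-matched lists, and that for skeletal muscle also without replicate 1 (0.105) and with the outermost start alone (0.0737), at differences to other genes of -22.5 and -23.6 points against -27.2. The lung list, by contrast, passed as less often marked with the outermost start alone (0.0105), and its median width, not called in the replicated list (0.672), was narrower without replicate 2 (0.0301), a turn from 241.5 bp above random lists to 871 bp below. It also lay below them with only touching peaks joined (-599 bp), with a −log10 q of at least 5 (-141.5 bp) and against lists matched on CpG number (-341.75 bp).

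Forebrain genes were marked at 16 of 19 members, which passed neither against other genes (Fisher exact, adjusted p = 0.194) nor against CpG-matched lists (permutation, 0.849). The widest domains were at the homeobox genes Dlx1 (6083 bp, or 1483 bp and 6531 bp in replicates 1 and 2), Emx1 (5002 bp, or 2474 bp and 2653 bp), Dlx2 (4312 bp) and at Pou3f2 (3672 bp). The unmarked members were Neurod6, Otx2 and Slc17a6. Without replicate 2, 18 of the 19 were marked and the list passed (0.0105), while the difference to other genes, 18.2 points, was 12.1 points without replicate 1 and 3.95 points with the start base inside a peak. Their median width did not pass (2469.5 bp against 2151 bp, permutation test, adjusted p = 0.368), and its difference of 318.5 bp turned to -190 bp with only touching peaks joined, -286 bp without replicate 2 and -746 bp against lists matched on CpG number.

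Germline genes were marked at 2 of 14 members (Fisher exact, adjusted p = 0.000530), although their promoters are not CpG-poor as a group (median ratio 0.628). CpG-matched lists averaged 81.2% marked (permutation, adjusted p = 0.00167). The marked genes were Brdt (1525 bp), at a downstream start only, and Dazl (935 bp). Ddx4, Mael, Mov10l1, Prm1, Stra8, Sycp1, Sycp3, Taf7l, Tex101, Tex11, Tnp1 and Zp3 were unmarked. Of 1092 olfactory receptor genes, 3 were marked (odds ratio 0.00121, 95% interval 0.000249 to 0.00355), namely Olfr94, Olfr1033 and Olfr658.

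The pools held both sexes, and genes of both sex chromosomes carried the mark. Xist, the non-coding RNA of the inactive X chromosome, had a domain of 3141 bp (3503 bp and 3126 bp in replicates 1 and 2) and its antisense gene Tsix 953 bp. On the Y chromosome Ddx3y (1684 bp), Uty (1723 bp, or 1077 bp and 1733 bp in replicates 1 and 2), Kdm5d (1079 bp) and Eif2s3y (1008 bp) were marked in both replicates, while Sry, Uba1y, Usp9y, Zfy1 and Zfy2 were not. Their X-linked counterparts Ddx3x, Kdm6a, Kdm5c and Eif2s3x were all marked, with 4573 bp, 3853 bp, 2792 bp and 1992 bp. The 13 protein-coding members did not pass for marking (Fisher exact, adjusted p = 0.773) and were marked less often than CpG-matched lists (permutation, 0.0140). Their widths did not pass (permutation test, adjusted p = 0.470), and the difference of -298 bp turned to 84.0 bp against lists matched on CpG number.

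Housekeeping genes were marked at 17 of 17 members (Fisher exact, adjusted p = 0.00267) and cell cycle genes at 16 of 16 (0.00435). CpG-matched lists averaged 97.3% and 98.3%, which full marking cannot pass. Housekeeping domains had a median of 3904 bp (permutation test, adjusted p = 0.000720), led by Actb (5267 bp), Tbp (4563 bp), Polr2a (4466 bp) and Ppia (4375 bp). Cell cycle domains had a median of 3081 bp (permutation test, adjusted p = 0.0108), led by the proliferation marker Mki67 (4395 bp), Plk1 (3704 bp), Mcm7 (3417 bp) and Pcna (3397 bp). The cell cycle width call ended without replicate 2 (0.0889), at an excess of 561 bp against 928.5 bp, and the housekeeping excess of 1748 bp was 913 bp with only touching peaks joined.

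Of the 20 widest domains, 13 lay at genes of the fixed lists, namely 8 gut mesenchyme genes, 3 Hox genes, 1 endoderm factor and 1 enteric gene. The widest spanned 31770 bp on chromosome 11 from 96297899 to 96329668 over Hoxb3 to Hoxb6, though it measured 15419 bp in replicate 1 and 38957 bp in replicate 2. Nr2f2, an orphan nuclear receptor gene, had 25118 bp (24882 bp and 25116 bp) on chromosome 7 from 70345701 to 70370818. A domain over Hoxa1, Hoxa2 and 5730596B20Rik had 24861 bp. Besides Meis2, Ptch1, Tbx2 and Meis1, the list held Six2 (15266 bp), Hoxa6 (14524 bp, shared with Gm28308, Hoxa3 and Hoxa5), Zfp503 (14460 bp, or 9599 bp and 14460 bp in replicates 1 and 2), Pitx1 (13528 bp), Foxa1, Foxf1 (12937 bp), Kdm6b (12899 bp), Barx1 (12662 bp), Bahcc1 (12390 bp), Hand2, Tnrc18 (12290 bp), Isl1 (12249 bp) and Nr2f1 (12153 bp). Barx1, a homeobox gene of stomach mesenchyme, measured 12339 bp and 12588 bp in replicates 1 and 2, on chromosome 13 from 48657624 to 48670285. The Kdm6b domain differed more, with 6177 bp and 13647 bp.

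The genes with the highest signal values were not those with the widest domains, and their domains ranged from 1448 bp to 5314 bp. Dnajc11 had the highest value, 69.5, in a domain of 1448 bp on chromosome 4 from 151933518 to 151934965. It was followed by Odf2 (67.6), the divergent pair Rsf1 and Aamdc, which share a peak, and Atxn2l (both peaks 67.4), Ssbp3 (67.2), Mtpn and Clptm1 (both 67.0), the chaperone gene Hsp90ab1 (66.6) and Ptma (66.1). Signal values at the 20 widest domains were lower, from 20.9 at Foxa1 to 59.1 at Tnrc18, with 28.5 at Barx1.

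Hox genes, the homeobox genes that pattern the body axis, had a wider median domain at low paralog numbers than at high ones. Of the 39 genes, 36 were marked (Fisher exact, adjusted p = 0.000782), and the unmarked were Hoxc11, Hoxc12 and Hoxd12. All 23 genes of paralog groups 1 to 8 were marked, with a median domain of 6257 bp (5660 bp and 6805 bp in replicates 1 and 2). Of the 16 genes of groups 9 to 13, 13 were marked, with a median of 1387 bp (1091 bp and 1278 bp). The ranges overlapped, from 960 bp to 31770 bp in groups 1 to 8 and from 276 bp to 6401 bp in groups 9 to 13. The difference thus holds for the medians and not for every gene. The split into these 2 parts was chosen after the values were seen and was not tested, since neighboring genes share domains. Replicated peaks covered 54.9% of the Hoxa cluster, on chromosome 6 from 52155590 to 52260880, and 37.3% of Hoxb, against 15.8% of Hoxc (12.1% and 15.3% in replicates 1 and 2) and 21.9% of Hoxd (12.5% and 21.5%). In covered length Hoxb held more than Hoxa, 64.8 kb against 57.8 kb. Its span of 173.9 kb includes the stretch between Hoxb13 and Hoxb9, where no replicated peak lay between positions 96194583 and 96270767. The list as a whole had wider domains than random lists (2866 bp, permutation test, adjusted p = 0.00300), a call that ended with only touching peaks joined (0.340) and, with the direction turned, against lists matched on CpG number (0.819). The excess of 716 bp was then 228 bp and -81.0 bp, and 4028.5 bp with peaks within 3 kb joined. CpG-matched lists averaged 92.8% marked, against 92.3% here, and full marking would not pass either.

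**Figure D5:**
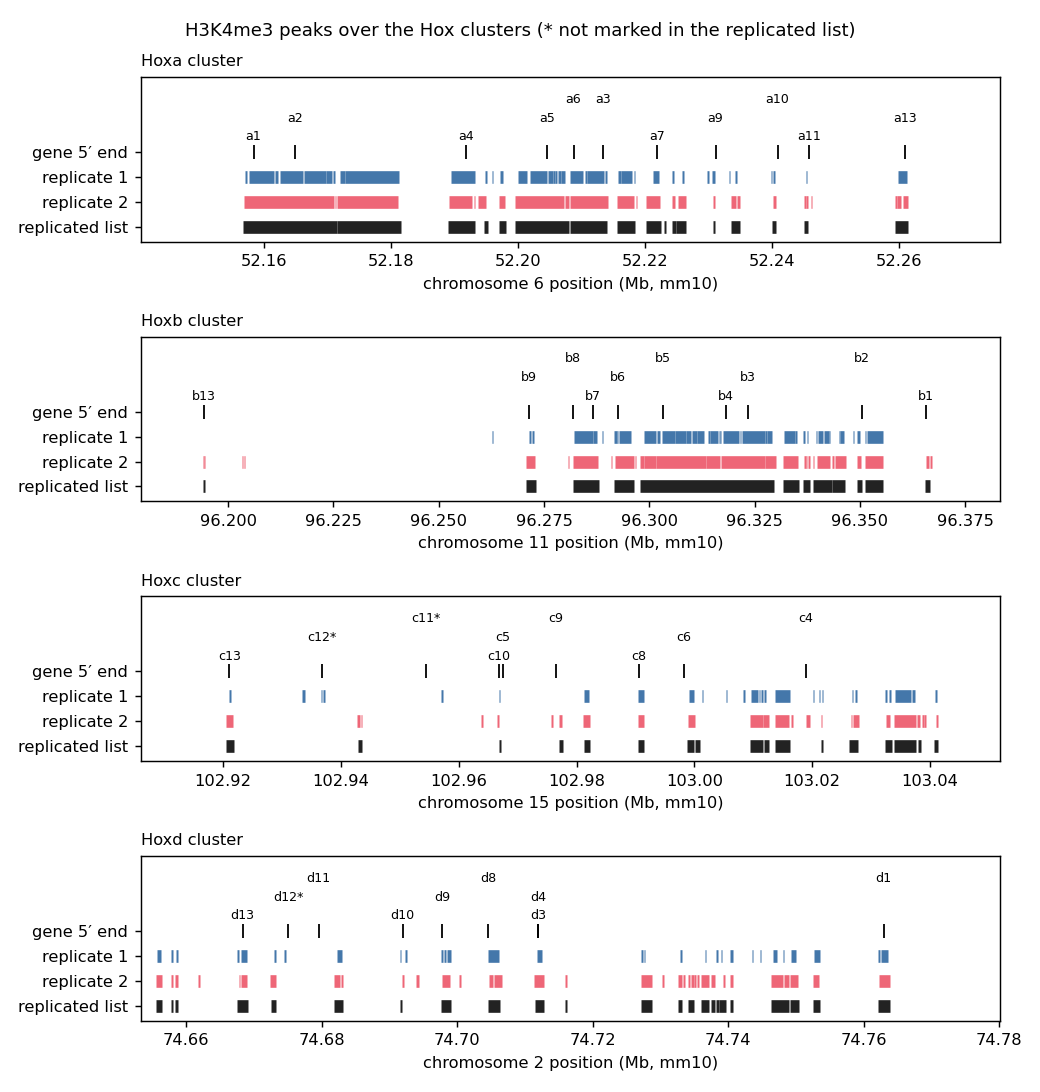
Maps of the Hox clusters on chromosomes 6, 11, 15 and 2 (x axis, position in Mb, mm10), with the peaks of each replicate and of the replicated list as blocks and the outermost annotated 5′ end of each gene as a tick. The widest replicated domains lie over Hoxb3 to Hoxb6 (31770 bp) and over Hoxa1 and Hoxa2 (24861 bp), and an asterisk stands for the 3 genes unmarked in the replicated list.

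Few genes were marked in a single replicate, and more of them in replicate 2. Replicate 2 alone marked 304 genes and replicate 1 alone 86 (exact McNemar test, p = 1.21e-29), which compares these libraries and not conditions. The counts were 493 and 22 with a −log10 q of at least 5, and replicate 1 alone marked 50 with at least 2. The threshold of 5 removed a larger part of the replicate 1 list (38.1%) than of the replicate 2 list (22.5%). No fixed list had more than 5 discordant genes, so none was able to pass the same exact test, whose smallest p with 5 is 0.0625. By signal value, the genes marked in replicate 2 only were led by Exoc3l (59.1), Sftpc (56.3), Oscar (48.7), Tnnc1 (44.8) and Lor (41.2), and at none of these 5 did a start base lie inside a replicated peak. Those marked in replicate 1 only were led by A630001G21Rik (5.56), the vasopressin gene Avp (5.14), Prss32 and Prss41, which share a peak (4.82), and Arhgap15 (4.45).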

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

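The test of a cell type more common in replicate 2 and those of cells from another organ were chosen only after the results were seen. The design has 1 group, so no biological explanation was tested against the technical ones.

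Peaks outside the main measurement appeared in 2 places. The replicated list held 12 peaks on 6 scaffolds outside the assembled chromosomes, with 20 scaffold peaks in replicate 1 and 12 in replicate 2, which the gene-based results left out. The pooled list marked 260 protein-coding genes that the replicated list did not, of which 50 were marked in replicate 1, 160 in replicate 2, some in both, and 61 in neither.

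Replicate 2 alone marked 304 genes and replicate 1 alone 86. The tables argue against wider replicate 2 peaks reaching over from a neighboring promoter as the main cause, since only 6.25% of the 304 genes had a replicate 2 peak that also overlapped a replicate 1 peak. Weak peaks may be why these genes were found in a single replicate. The median −log10 q at the other 285 genes lay at percentile 20.3 of the replicate 2 list, which met the bar set before it was seen. Genes marked in replicate 1 only were as weak in their own list (percentile 14.0), a comparison outside that prediction. Weak peaks on both sides leave open why more genes were found in replicate 2. A cell type more common in the replicate 2 pool stays open too, as no list had more than 5 such genes and the exact McNemar test (lowest adjusted p = 1.00) cannot go below p = 0.0625 with 5.

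Promoters of genes on the lists of other organs were marked, such as Dlx1 and Emx1 of the forebrain list. Of 69 CpG-poor markers of liver, intestine, lung, heart, skeletal muscle and pancreas, 9 were marked (percentile 0.215 among CpG-matched lists, which averaged 25.5%). At 2 of them a start base lay inside a peak (percentile 0, average 21.9%). These shares cannot decide on cells from these organs. Whether the markers carry the mark in their own organ at day 14.5 was not examined, and CpG-matched genes do not show what foreign cells would give. Taken by itself, no full list of these 6 organs lay below CpG-matched lists (permutation, adjusted p = 0.139 to 1.00), so cells of a single organ stay open too. Promoters rich in CpG, which carry the mark in many tissues, may account for the marking of such genes, as the forebrain share lay at percentile 11.2 of CpG-matched lists. A share of foreign cells too small to give a called peak stays open, and the marker test did not cover forebrain cells.

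Domains at gut mesenchyme and endoderm transcription factor genes were wide. Long CpG-rich stretches are argued against as the whole cause, since the median widths of both lists lay at percentile 100 among marked genes matched on CpG number within 5 kb. The joining of separate peaks made up part of the gut mesenchyme excess over random lists, which fell from 5715 bp to 3689 bp with only touching peaks joined. It is argued against as the whole cause, since the median of 5762 bp stayed above the 2073 bp of random lists (permutation test, adjusted p = 0.00120, from the smallest p that 10000 random lists allow, as under each other alternative). A hypothesis is that the width follows regulation of these genes in the stomach, and no expression data were used here to test it.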

How the results depend on the processing

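Requiring the start base inside a peak and matching on CpG number within 5 kb were chosen after seeing the data. Marked gene counts stayed within 1.5 times the main count under all 9 alternatives (13690 to 14730 genes). With an overlap of at least 50% of the peak, 78.9% and 72.6% of replicate 1 and 2 peaks were shared, and 88.0% and 97.9% of replicated peaks were found in replicates 1 and 2. With a −log10 q of at least 2 the shares of replicate 1 and 2 peaks were 90.1% and 79.9% and the Jaccard index 0.755. With at least 5 the shares were 98.7% and 85.1% and the index 0.769. The threshold of 5 removed 38.1% of the replicate 1 list and 22.5% of the replicate 2 list. The cause of these shifts was not tested. The thresholds of 2 and 5 left 50 and 22 genes marked in replicate 1 only, and 5 left 493 in replicate 2 only. A 2 kb window put 81.4% of peaks at starts, and the lists of single replicates 65.5% to 70.2%. Comparing replicates has no value without either of them.

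Against CpG-matched lists, 2 lists were more often marked and 3 less often, in place of 8 and 8. For gut mesenchyme, gut patterning, housekeeping, cell cycle and Hox genes a share of 100% lies within the central 95% of matched lists, so the matched test was not able to call them more often marked. The endoderm factor and epithelial lists, fully marked, lay above that range and did not pass after adjustment, with no higher share possible. The difference to the matched lists changed sign for squamous (4.95 points), erythroid (8.37), forebrain (-6.14) and Hox genes (-0.451). Of the 25 lists, marking kept its direction and call for all under both other windows and both q thresholds, for 23 with the outermost start, for 24 with the start base inside a peak, and for 23 and 24 without replicates 1 and 2.

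Domain width differences to random lists, in bp, changed sign as follows, and the cause was not tested. With only touching peaks joined they were -538.5 for squamous, 40 for endothelium, -455.5 for pancreas, -599 for lung and -190 for forebrain. Joining within 3 kb gave 741 for endothelium, and a −log10 q of at least 5 gave 13 for endothelium and -141.5 for lung. Matching on CpG ratio gave -72.0 for mesothelium, 355 for endothelium and 10 for erythroid genes. Matching on CpG number gave -406 for mesothelium, -341.75 for lung, -746 for forebrain, -81.0 for Hox and 84.0 for sex-linked genes. Leaving out a replicate gave ranges of -611 to 672 for squamous, 49.0 to 281.5 for endothelium, -279 to 426 for pancreas, -871 to 557.5 for lung and -286 to 533 for forebrain, and 1 to 2 narrower lists. Only the Hox list among these had a call in the main test. Without replicate 2 the width calls of 3 lists ended, and 219 of the 320 named domain widths moved by more than the spread between replicates, against 95 without replicate 1. Read depth is unknown, so its part in these changes was not tested.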

Other observations

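The genes of this part, and the test of another gene's start inside the peak, were chosen after the values were seen. Col3a1, Mfap4, Emilin1 and Col6a1, which encode extracellular matrix proteins, were among the 41 genes of low promoter CpG ratio with a peak of their own, and the group was not tested for enrichment. Col3a1, a fibrillar collagen gene with a CpG ratio of 0.184, had a domain of 5074 bp (4906 bp and 5426 bp in replicates 1 and 2) on chromosome 1 from 45311127 to 45316200. Mfap4, Emilin1 and Col6a1 had 2936 bp, 3260 bp and 2527 bp. Among long non-coding genes, 2478 of 10150 were marked, 655 of them in a domain that no protein-coding start shares. Carmn, a smooth muscle RNA gene, had the widest of these, 11342 bp on chromosome 18 from 61655214 to 61666555 (9904 bp and 11204 bp in the replicates). Malat1 had 8534 bp and Dnm3os, which hosts microRNAs of mesenchyme, 7360 bp.

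Separate groups of annotated starts of the same list gene often differed in the mark. Starts were taken from all annotated transcripts, and whether an unmarked group is a promoter at all was not tested. Of 135 genes with groups of starts over 5 kb apart, 84 had some groups marked and others not, 13 had all marked and 38 none. At Hnf4a the upstream start at position 163506808 of chromosome 2 was marked and the downstream group from 163546817 was not. At Trp63 the internal start at 25801916 of chromosome 16 was marked, and the upstream group at 25683763 was not. At Runx1, on the minus strand of chromosome 16, the group from 92695495 was marked and the upstream group from 92825778 was not.

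A first hypothesis was that germline genes lack the mark because their promoters are CpG-poor. The list lay at percentile 0 among CpG-matched lists, with 14.3% marked against 81.2% on average, which argues against CpG content as the whole cause. Other ways of silencing them were not tested.

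Another hypothesis was that CpG-poor promoters are counted as marked through another promoter. Of the 98 marked genes in the lowest 2 of 10 equal groups by CpG ratio, 58.2% had no start base inside a peak (54 genes) or shared that peak with another protein-coding gene (3 genes), and 41 had a peak of their own. Of the 54, the nearby peak held the start of another protein-coding gene at 18 and no annotated start at 36. Another protein-coding start was thus found in the peak of 21.4% of the 98 genes, which argues against a neighboring promoter as the source for most. The share of 58.2% had passed the bar of 50% set before it was seen, but it counts the 36 genes without such a promoter.

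A further hypothesis, formed from the names of the unmarked genes but before its value was seen, concerned CpG-rich genes without the mark. Of the 6574 genes in the highest 3 of 10 equal groups by CpG ratio, 35 were unmarked in the replicated list, and 29 of these in the other lists too. Duplicated sequence that filtered alignments cannot place may account for most of them: 65.7% (23 genes) had most of their promoter 50-mers at another place in the genome, against 0.214% of the 6539 marked genes. These include histone genes of chromosome 13 such as Hist1h2ao, the pair Entpd4 and Entpd4b, and Srp54b. Cntfr, Kcnk9, Otx2, Yy2, Zfp541, Hsf5, Tnnt1, Esx1, Ermard and Hoxc12 each had at least 1 start with no repeated 50-mer around it. Repeats thus do not explain why the replicated list left that start out. Only the least repeated start of a gene was counted, so other starts of these genes may lie in repeated sequence. Of these genes, Tnnt1 was marked in both replicates, Otx2 and Hoxc12 in replicate 1 and Esx1 in replicate 2. The read length is not given in the sources used here, and reads of another length would change which promoters count as repeated.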
